A study of Mus musculus with 45 samples.

How the data were processed

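Total RNA from the hearts of 45 mice was labelled with biotin from 3 µg per mouse and hybridized to 1 Affymetrix mouse array each, and the labels describe the arrays of a group as biological replicates. The labels disagree on the exposure: the growth protocol speaks of an LPS study, while the titles and the treatment protocol name cigarette smoke, which was followed here. The deposited values are log2 expression values per probe set. The submitters' processing notes name RMA (background correction, quantile normalization between arrays and summary per probe set) without a version, and its software and settings, the arrays processed together and the scan dates are not given in the sources used here. The values ranged from 2.12 to 14.77, and the array medians from 6.20 to 6.24. The labels name no batch and no depth applies to arrays, whose number limits the precision.

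The deposited table held 22690 probe sets, of which 64 were controls. The array annotation listed 21084 of them with a gene, 20393 with 1 gene and 691 with several, and 1606 were not listed. Of the probe sets with 1 gene, 20364 were matched to a RefSeq gene by Entrez identifier and 0 symbols needed an update. They covered 12393 genes, 4956 of them with several probe sets, and the probe set with the highest mean over the 45 arrays stood for its gene. The lowest 25% of genes by mean (below 4.90) were left out, and 9295 genes were tested. Probe sets with several genes or none were tested apart.

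Group means of all 45 arrays were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, 42.6 residual degrees of freedom including the prior, two-sided). Figures and tables were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. The comparisons were each smoke against air within a diet, the diet in air, sidestream against mainstream smoke within a diet, and for each smoke the interaction (the effect in DIO minus the effect in RW mice). P values were adjusted by Benjamini-Hochberg within a comparison, with a threshold of 0.05. The 42 lists of genes were tested with camera at a preset correlation of 0.01 and, as an alternative, an estimated correlation, with adjustment over the lists of a comparison. Beside each list the members past the threshold were counted over all genes and adjusted over the list alone.

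The comparisons, tests, filter, lists and most alternatives were fixed before the data were examined, and so was the rule for the genes that are named. For smoke against air and the diet in air, these were the 10 largest rises and the 10 largest falls among genes past the threshold, leaving out unnamed clones, and up to 4 genes with the smallest adjusted p from each list past its threshold. For the other comparisons they were the 5 largest rises and falls. A fixed panel of genes could be named in any comparison, among them Cyp1a1, Cyp1b1, Nqo1, Hmox1, Mt1, Mt2, Vegfa, Angptl4, Pdk4, Ucp3, Hspa1b, Hspa5, Nppa, Nppb, Myh7, Dbp, Per2, Arntl, Fkbp5, Cdkn1a, Lcn2, Adipoq, Col1a1 and Acta2. Other genes are given as chosen after their values were seen.

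The procedure was tested on simulated data with the same group sizes, in which 200 of 9295 genes were changed. Each gene was drawn independently from a normal distribution with its own spread. Variation that genes share in the real arrays, and single odd arrays, were thus left out. The shares that follow hold for such data and need not hold for the real arrays. For the comparisons of 2 groups it recovered 67.5% to 78% of genes changed 1.2-fold, 96% to 99% of those changed 1.5-fold and 98% to 100% of those changed 2-fold. For the interactions it recovered 45% (mainstream) and 39% (sidestream) at 1.2-fold, 93% and 94% at 1.5-fold, and 98% and 96.5% at 2-fold, and 0% had the wrong sign. Of the genes called in a simulation, 0.6% (DIO-SS at 1.2-fold) to 8.4% (mainstream interaction at 2-fold) had not been changed.

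Comparisons that share control arrays also share chance values. Their correlation and covariance across genes were set beside 100 draws of simulated unchanged groups and beside values with the shared arrays divided at random. For the simulated covariance only the mean of the draws was kept. Without a range it cannot show whether a covariance exceeds chance. Shared genes were counted beside the number expected by chance for independent comparisons. The carry-over of smoke genes from RW to DIO mice was measured for the 200 genes with the smallest p in one part of the RW mice, in the other part and in all DIO mice, over 100 divisions, with bootstrap intervals over mice. Array quality was read from the correlation with the own group, the 3' minus 5' differences of Actb and Gapdh and the marker lists of other tissues.

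The alternatives were no filter or a stricter filter, the mean of all probe sets or every probe set, eBayes with trend and robust settings, array weights, only the groups compared, a further quantile normalization, the replicate number of the title or the number in the description as a block, that number as a covariate, the mean of atrial or adipocyte markers as a covariate, and leaving out each array in turn. For the lists, the atrial covariate and leaving out RW-MS 2, 6 and 8 were added after seeing the data. The replicate numbers showed no pairing: residuals of arrays with the same title number correlated at -0.003 and those with other numbers at 0.001. Comparisons across smoke and diet at once, such as DIO-SS against RW-MS, were not made.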

Results

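Gene expression was measured in the hearts of 45 male C57BL/6 mice on one-colour oligonucleotide arrays, 1 mouse per array. Regular weight (RW) mice ate a standard diet with about 5 kcal% fat, and diet-induced obese (DIO) mice ate a diet with 60 kcal% fat from 6 weeks of age, 9 weeks before exposure. From 15 weeks of age the mice breathed filtered air (SC, the sham control), mainstream smoke (MS, drawn through the cigarette) or sidestream smoke (SS, given off at its burning tip) through the nose for 5 h a day. They had 8 exposures within 2 weeks, and hearts were taken on the next day. The groups held 8 RW-SC, 8 RW-MS, 7 RW-SS, 8 DIO-SC, 6 DIO-MS and 8 DIO-SS arrays. The median of all probe sets lay between 6.20 and 6.24 log2 units on every array, and the number of arrays limits the precision. The title of the series asks whether obesity from a high-fat diet impairs the heart's transcriptional response to cigarette smoke. The comparisons therefore took smoke against air within each diet, the diet in air, the 2 smokes against each other, and the difference between the smoke effects of the 2 diets. Changes are log2 differences between group means ± the standard error (SE) of limma, and an array count such as "8 of 8" gives the smoke-exposed or DIO arrays on the called side of the control mean. Changes called robust kept their call in every alternative that tested them and without any 1 array.

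**Figure D1:**
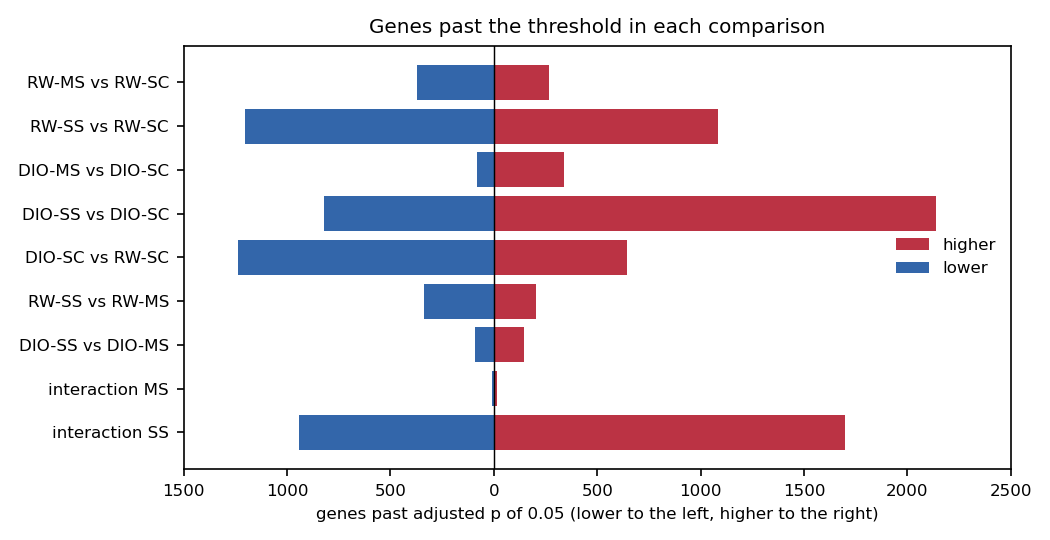
Number of genes past an adjusted p of 0.05 (x axis, genes lower to the left and higher to the right) in each of the 9 comparisons (y axis). Sidestream smoke gave 2288 genes in RW and 2960 in DIO mice, and the interaction with diet gave 2641 for sidestream and 21 for mainstream smoke.

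Mainstream smoke in regular weight mice (RW-MS against RW-SC, the response to mainstream smoke without obesity) went with lower Tfrc, Nr1d1, Kcne1 and Nppb, among others. Tfrc (1452661_at), the transferrin receptor that brings iron into cells, fell by 1.76 ± 0.18 (limma adjusted p = 1.39e-08, n = 8 and 8), from 10.22 ± 0.21 (SD) to 8.46 ± 0.38, in 8 of 8 arrays. The mean of all Tfrc probe sets gave a change of -0.87. Nr1d1 (1426464_at), a repressor in the circadian clock, changed by -0.90 ± 0.08 (adjusted p = 9.65e-11), and the potassium channel subunit Kcne1 (1420672_at) by -1.06 ± 0.14 (adjusted p = 1.58e-06), each lower in 8 of 8 arrays. Nppb (1450791_at), which encodes the natriuretic peptide released by stretched ventricle, changed by -0.79 ± 0.16 (adjusted p = 0.00119) in 8 of 8 arrays. The labels give no times of killing or feeding per group. Clock genes such as Nr1d1 and Dbp vary with both, so in all comparisons their differences between groups need not come from smoke or diet.

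With limma, 638 of 9295 genes passed, 266 higher and 372 lower, of which 2 rose and 14 fell at least 1.5-fold. After a further quantile normalization 675 passed, 332 higher and 343 lower, and with array weights 896, 450 higher and 446 lower. With the mean of the atrial list in the model 562 genes passed, and 380 of the 638 were among them. Other robust falls were Klhdc8a (-0.82), Tnfrsf12a (-0.67, a receptor for the cytokine TWEAK), Plin5 (-0.40, a lipid droplet coat protein), Bhlhe40 (-0.38) and Dbp (-0.33, a clock output gene), with adjusted p between 1.55e-08 and 0.00543. Tent5c, a poly(A) polymerase, had the largest rise (0.84 ± 0.25, adjusted p = 0.0297, 7 of 8 arrays), and its call ended without RW-SC 4, 5 or 8 or RW-MS 3, 5, 7 or 8 (adjusted p between 0.0507 and 0.0679). The iron transporter of mitochondria Slc25a37 rose by 0.61 ± 0.16 (adjusted p = 0.0161) and Gclm, a subunit of the enzyme that makes glutathione, by 0.56 ± 0.08 (adjusted p = 6.53e-06). Nampt, of NAD synthesis, rose by 0.53 ± 0.07 (adjusted p = 1.58e-06) and Glul (1426236_a_at), glutamine synthetase, by 0.46 ± 0.05 (adjusted p = 8.73e-08), and all 4 genes were higher in 8 of 8 arrays. Cyp1a1, the target of the aryl hydrocarbon receptor that breaks down smoke hydrocarbons, was not past the threshold (0.18 ± 0.12, adjusted p = 0.415). Neither were the antioxidant genes Nqo1 (0.09, adjusted p = 0.537) and Hmox1 (0.24, adjusted p = 0.176). The clock list was not past in RW-MS (1 gene higher, 4 lower and 13 not past of 18, adjusted p = 0.75).

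Of the 42 lists of genes, 9 passed in RW-MS, 4 up and 5 down, by camera with a preset correlation. Among 36 extracellular matrix genes 8 fell, 0 rose and 28 did not pass, and 13 passed when adjusted over the list alone (adjusted p = 5.54e-08, and adjusted p = 0.435 with an estimated correlation). Col4a2, a basement membrane collagen, changed by -0.30 (adjusted p = 0.00155). Among 26 unfolded protein response genes 8 fell, 1 rose and 17 did not pass, with 9 past when adjusted over the list alone (adjusted p = 0.00253, and adjusted p = 0.435 with an estimated correlation). The chaperone Hspa5 (-0.25, adjusted p = 0.00205) and the secreted factor Manf (-0.48, adjusted p = 0.00157) were among them. Among 27 hypoxia genes 6 fell and 2 rose, with 10 past when adjusted over the list alone (adjusted p = 0.00307, and adjusted p = 0.435 with an estimated correlation). The falls included Tfrc (-1.76), already named above, and hexokinase Hk1 (-0.26, adjusted p = 2.18e-06). The hypoxia list was not tested without Tfrc. The 15 fibroblast markers shifted down as a list with 0 members past over all genes and 4 past when adjusted over the list alone (adjusted p = 0.0015, and adjusted p = 0.576 with an estimated correlation). The mean of the fibroblast list was -0.33 in RW-MS 2, 6 and 8, the arrays nearly without atrial transcripts, -0.02 in the other RW-MS arrays and 0.02 in RW-SC. That of the extracellular matrix list was -0.33, -0.06 and 0.04. Without these 3 arrays, a test chosen after seeing the data, the adjusted p was 0.632 for fibroblast markers, 0.0957 for the unfolded protein response, and 0.0186 for extracellular matrix and for hypoxia. With the mean of the atrial list in the model, also chosen after seeing the data, it was 0.962, 0.094 and 0.0598 for the first 3, and hypoxia still passed.

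The glucocorticoid response list rose in RW-MS, with 5 of 26 genes higher, 1 lower and 11 past when adjusted over the list alone (adjusted p = 0.00879, and adjusted p = 0.462 with an estimated correlation). Its higher members included Cebpb (0.43, adjusted p = 2.36e-05) and Gadd45a (0.39, adjusted p = 0.000764). Fatty acid oxidation also rose as a list, with 4 of 38 genes higher, 1 lower and 7 past when adjusted over the list alone (adjusted p = 0.00765, and adjusted p = 0.804 with an estimated correlation). The higher genes included the carnitine carrier Slc25a20 (0.26, adjusted p = 1.63e-05) and the thiolase Acaa2 (0.19, adjusted p = 0.00405). Proteasome genes moved by a list median of 0.05, with 2 of 23 higher and 2 past when adjusted over the list alone (adjusted p = 0.000895, and adjusted p = 0.435 with an estimated correlation). The 6 red cell markers had 0 members past over all genes and 5 past when adjusted over the list alone, with a list median of 0.32 (adjusted p = 0.00214, and adjusted p = 0.435 with an estimated correlation). Alas2 (1451675_a_at), the first enzyme of heme synthesis in red cells, was at 0.68 ± 0.22 (adjusted p = 0.0532). The list, which holds Alas2, marks cells that a heart sample can carry. In all comparisons its changes may reflect the amount of blood in the samples rather than heart cells, which was not tested. Without RW-MS 2, 6 and 8 the fatty acid oxidation list was not past (adjusted p = 0.518), and with the atrial mean in the model neither it (0.677) nor the proteasome list (0.0566) was.

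Atrial transcripts were nearly missing from 3 of the 8 RW-MS arrays (RW-MS 2, 6 and 8). Sln (1420884_at), the atrial regulator of the calcium pump, lay between 4.47 and 5.42 in these 3 arrays, at 12.16 or more in the other RW-MS arrays and at 11.43 or more in every other group. Sln changed by -2.72 ± 0.82 (adjusted p = 0.0338) with 5 of 8 arrays lower, and the atrial light chain Myl7 (1449071_at) by -2.48 ± 0.74 (adjusted p = 0.0325). The list had 4 of 13 genes lower, 0 higher and 8 past when adjusted over the list alone (adjusted p = 2.57e-05, and adjusted p = 0.435 with an estimated correlation). Without RW-MS 2, 6 or 8 the adjusted p was 0.0964, 0.109 and 0.109 for Sln and 0.0908, 0.104 and 0.101 for Myl7. Without RW-SC 3, 5 or 7 it was 0.0532, 0.0539 and 0.0524 for Sln and 0.0506, 0.0504 and 0.0522 for Myl7, and the Sln call also ended without RW-SC 2 (0.0509) or RW-SC 6 (0.0511). With the mean of the atrial list in the model, Sln was at -0.11 (adjusted p = 0.857) and Myl7 at -0.13 (adjusted p = 0.817). That mean holds both genes, so their changes had to shrink, and no conclusion is drawn from these values. The mean of all Sln probe sets gave -1.49 (adjusted p = 0.0513).

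**Figure D2:**
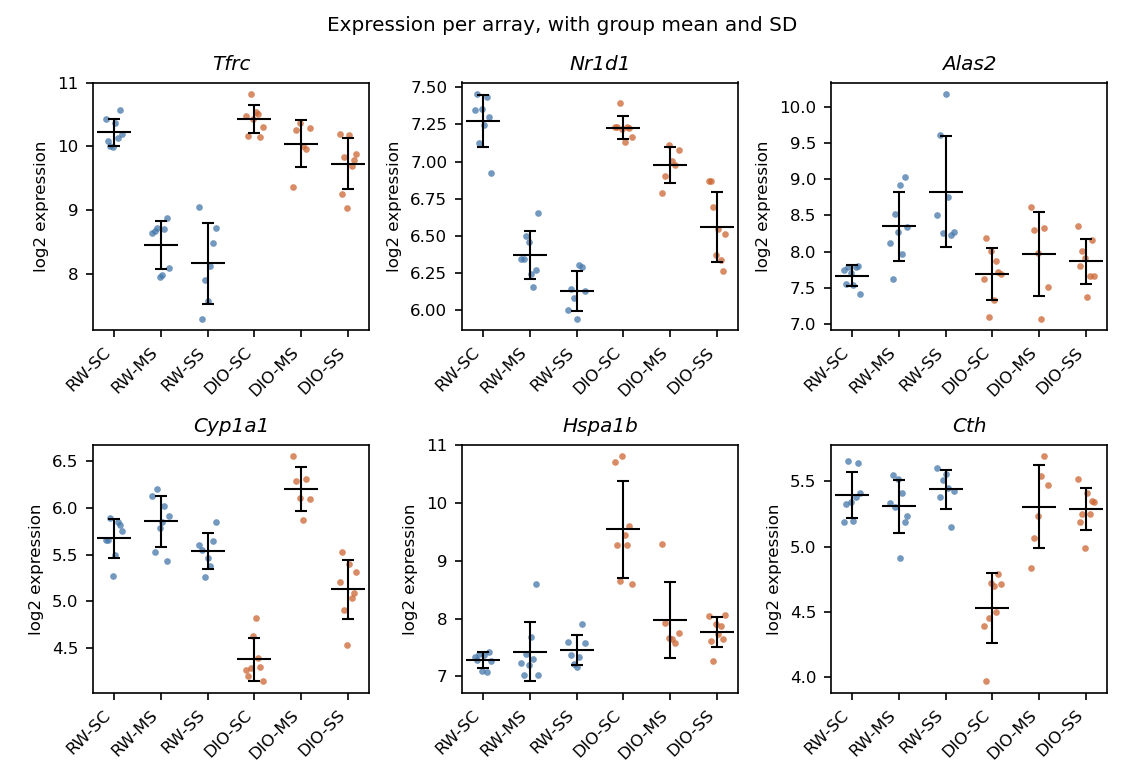
Log2 expression (y axis) of 6 genes in each array (points) of the 6 groups (x axis, RW blue and DIO orange), with the group mean (bar) and SD (whiskers). Tfrc and Nr1d1 were lower in every smoke-exposed RW array than in any RW-SC array, and Cyp1a1 was lower in every DIO-SC than in any RW-SC array.

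Sidestream smoke in regular weight mice (RW-SS against RW-SC, the response to sidestream smoke without obesity) went with lower Tfrc, Nr1d1 and Dbp and higher Alas2, Ddit4 and Tent5c. Tfrc fell by 2.05 ± 0.19 (adjusted p = 2.3e-10, n = 7 and 8), to 8.17 ± 0.63, in 7 of 7 arrays, and by 1.05 as the mean of its probe sets. Nr1d1 changed by -1.15 ± 0.08 (adjusted p = 9.07e-14) and Dbp (1438211_s_at) by -1.03 ± 0.08 (adjusted p = 1.29e-12), each lower in 7 of 7 arrays. Alas2 rose by 1.16 ± 0.23 (adjusted p = 0.000244), the stress-induced growth inhibitor Ddit4 by 1.09 ± 0.18 (adjusted p = 1.7e-05) and Tent5c by 1.46 ± 0.26 (adjusted p = 3.94e-05), each in 7 of 7 arrays.

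With limma, 2288 of 9295 genes passed, 1083 higher and 1205 lower, of which 14 rose and 29 fell at least 1.5-fold. After a further quantile normalization 2160 passed, 1131 higher and 1029 lower. Array RW-SS 7 had a 3' minus 5' difference of 0.94 for Gapdh, a measure of RNA integrity, where the other RW-SS arrays reached 0.30, and 2299 genes passed without it. Kcne1 (-0.83), Nppb (-0.82), Klhdc8a (-0.85) and Bhlhe40 (-0.77) were lower with adjusted p between 8.56e-11 and 0.000277. Glul rose by 0.69 ± 0.05 (adjusted p = 1.29e-12), and Pdk4 (1417273_at), which restrains pyruvate oxidation in mitochondria, by 0.74 ± 0.19 (adjusted p = 0.00313) in 6 of 7 arrays. Of the antioxidant genes, Hmox1, heme oxygenase, rose by 0.63 ± 0.11 (adjusted p = 3.17e-05) and Nqo1 by 0.33 ± 0.07 (adjusted p = 0.000877), each in 7 of 7 arrays. The metallothionein Mt2 rose by 0.50 ± 0.13 (adjusted p = 0.00504) in 5 of 7. Cyp1a1 was not past the threshold (-0.14 ± 0.12, adjusted p = 0.432).

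In RW-SS 3 of the 42 lists passed, 2 up and 1 down. All 6 red cell markers rose, and 6 passed when adjusted over the list alone (adjusted p = 0.00123, and adjusted p = 0.662 with an estimated correlation). They included the anion exchanger Slc4a1 (0.55, adjusted p = 0.00432) and Bpgm, which makes the regulator of oxygen release (0.71, adjusted p = 0.00102). The list mean was 1.08 in RW-SS 4 and 0.80 in RW-SS 2. It lay between -0.06 and 0.31 in the other RW-SS arrays and at -0.11 or less in RW-SC. The glucocorticoid response list had 11 of 26 genes higher, 0 lower, 15 not past and 12 past when adjusted over the list alone (adjusted p = 0.000318, and adjusted p = 0.662 with an estimated correlation). Cebpb (0.63, adjusted p = 1.03e-08) and Tsc22d3, a glucocorticoid-induced leucine zipper (0.48, adjusted p = 1.66e-05) were among them. Extracellular matrix fell as a list, with 11 of 36 genes lower, 2 higher, 23 not past and 14 past when adjusted over the list alone (adjusted p = 0.0107, and adjusted p = 0.951 with an estimated correlation). The collagen chaperone Serpinh1 (-0.64, adjusted p = 0.000363) and Col4a2 (-0.47, adjusted p = 8.24e-07) were among them. The call of that list ended without RW-SC 1 (adjusted p = 0.0507), RW-SS 2 (0.0556) or RW-SS 4 (0.0915). Circadian clock genes moved both ways (3 higher, 5 lower and 10 not past of 18), and the list was not past (adjusted p = 0.15).

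The responses to the 2 smokes in RW mice shared genes and direction: 197 genes rose and 274 fell in both, where 31 and 48.2 would be shared by chance, and 0 went opposite ways. These chance counts take the responses as independent, while shared control arrays alone raise the overlap. The log2 changes correlated across genes with r = 0.62 (genes are not independent replicates). Both responses were taken against the same RW-SC arrays, and unchanged groups simulated with these arrays gave r = 0.49 (between 0.12 and 0.81 in 100 draws). The covariance was 0.0121 against 0.00342 in the simulation, and with the control arrays divided between the responses it was 0.00951 and r was 0.43.

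The high-fat diet in air (DIO-SC against RW-SC, the state of the obese heart without smoke) went with higher Pdk4, Acot1, Hspa1b and Hspa1a and lower Slc2a1 and Cyp1a1, among others. Pdk4 rose by 1.85 ± 0.18 (adjusted p = 3.07e-10, n = 8 and 8), from 9.90 ± 0.21 (SD) to 11.76 ± 0.21, and Acot1 (1449065_at), which releases fatty acids from coenzyme A, by 1.2 ± 0.12 (adjusted p = 2.3e-10), each in 8 of 8 arrays. Hspa1b (1452318_a_at), the inducible heat shock protein of the Hsp70 family, rose by 2.26 ± 0.24 (adjusted p = 2.44e-09) and Hspa1a by 1.81 ± 0.22 (adjusted p = 4.73e-08), in 8 of 8 arrays. The glucose transporter Slc2a1 fell by 0.75 ± 0.07 (adjusted p = 3.2e-11) and Cyp1a1 (1422217_a_at) by 1.29 ± 0.12 (adjusted p = 9.96e-11), each in 8 of 8 arrays and below every RW-SC array. The DIO-SC mean of Cyp1a1 lay below 4.90, the cut for dim genes, as did that of Cth, named below. In all comparisons with DIO-SC hearts the sizes of the changes of these genes are thus less certain.

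With limma, 1882 of 9295 genes passed, 643 higher and 1239 lower, and 16 rose and 24 fell at least 1.5-fold. After a further quantile normalization 1680 passed, 857 higher and 823 lower. Fatty acid oxidation had 29 of 38 genes higher, 1 lower (Ppara, -0.18, chosen after its values were seen), 8 not past and 33 past when adjusted over the list alone (adjusted p = 2.96e-37, and adjusted p = 0.00513 with an estimated correlation). Its members included Slc25a20 (0.53), the carnitine palmitoyltransferase Cpt2 (0.49), the reductase Decr1 (0.45), the uncoupling protein Ucp3 (0.86) and the fatty acid transporter Cd36 (0.32), with adjusted p between 4.67e-13 and 2.41e-05. Heat shock had 15 of 23 genes higher, 0 lower, 8 not past and 17 past when adjusted over the list alone (adjusted p = 5.62e-14, and adjusted p = 0.0281 with an estimated correlation). The co-chaperone Dnaja1 (0.83, adjusted p = 7.04e-09) and the mitochondrial chaperonin Hspd1 (0.27, adjusted p = 6.2e-08) were among them. Immediate early genes had 6 of 25 higher, 0 lower, 19 not past and 7 past when adjusted over the list alone (adjusted p = 1.1e-05, and adjusted p = 0.0281 with an estimated correlation). Jun (0.54, adjusted p = 5.89e-06) and Ier3 (0.37, adjusted p = 1.45e-06) were among them. These 3 lists, all in this comparison, were the only ones of the 52 list results past the threshold that held with an estimated correlation.

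Another 4 lists passed in the diet comparison. Glucocorticoid response had 11 of 26 genes higher, 1 lower and 14 past when adjusted over the list alone (adjusted p = 3.22e-05, and adjusted p = 0.16 with an estimated correlation). Sgk1 (0.66, adjusted p = 1.25e-06) and Fkbp5 (0.53, adjusted p = 0.00494) were among them. Glycolysis had 7 of 26 genes lower, 0 higher and 7 past when adjusted over the list alone (adjusted p = 0.0265, and adjusted p = 0.94 with an estimated correlation), with the insulin-responsive transporter Slc2a4 at -0.24 (adjusted p = 4.41e-05) and hexokinase Hk2 at -0.26 (adjusted p = 2.49e-05). That list was not past without DIO-SC 2 (adjusted p = 0.0957). Endothelial genes had 6 of 33 higher, 1 lower and 7 past when adjusted over the list alone (adjusted p = 0.0209, and adjusted p = 0.401 with an estimated correlation). The list was not past with dim genes kept (adjusted p = 0.073). Vegfa, the growth factor for endothelium, rose by 0.31 ± 0.06 (adjusted p = 0.000531).

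Lipid and sterol synthesis had 13 of 24 genes lower, 1 higher (Gpam, 0.57), 10 not past and 16 past when adjusted over the list alone in DIO-SC (adjusted p = 0.00794, and adjusted p = 0.822 with an estimated correlation). Scd1 (1415964_at), the desaturase that makes oleate, changed by -2.88 ± 0.69 (adjusted p = 0.00245) and fatty acid synthase Fasn by -2.18 ± 0.58 (adjusted p = 0.00596), each lower in 8 of 8 arrays and below every RW-SC array in 5. Fat cell markers differed between the same arrays: the mean of the adipocyte list, relative to its mean over all arrays, was -0.44 in DIO-SC and 0.24 in RW-SC. Of its 11 genes 1 rose and 2 fell, the list was not past (adjusted p = 0.634), and Adipoq was at -1.90 ± 0.93 (adjusted p = 0.144). With that adipocyte mean in the model Scd1 was at -1.61 and Fasn at -1.10, and with the brown fat mean at -1.89 and -1.33, all past the threshold.

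**Figure D3:**
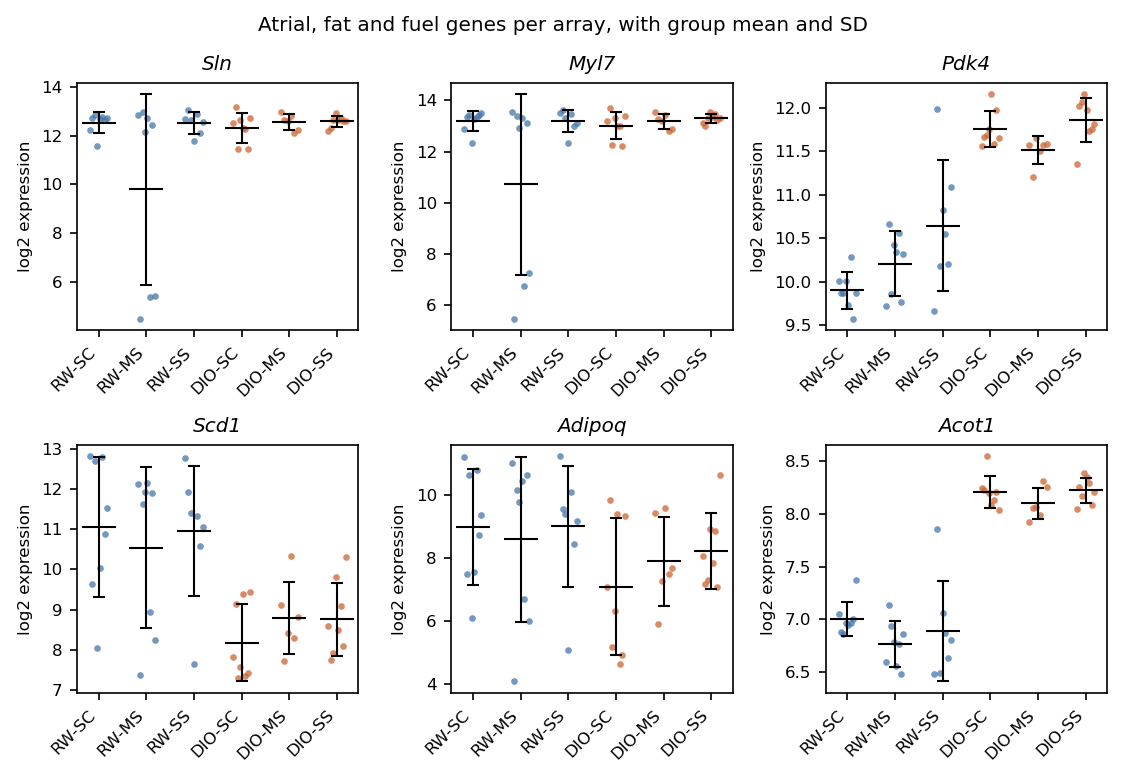
Log2 expression (y axis) of atrial (Sln, Myl7), fuel (Pdk4, Acot1) and fat-related genes (Scd1, Adipoq) in each array (points) of the 6 groups (x axis, RW blue and DIO orange), with the group mean (bar) and SD (whiskers). Sln and Myl7 were low in 3 RW-MS arrays, and Pdk4 and Acot1 were higher in every DIO-SC than in any RW-SC array.

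Mainstream smoke in obese mice (DIO-MS against DIO-SC, the response to mainstream smoke on the high-fat diet) went with higher Cyp1a1 and Cth and lower Hspa1b and Ptgds. Cyp1a1 rose by 1.81 ± 0.13 (adjusted p = 9.74e-14, n = 6 and 8), from 4.38 ± 0.23 (SD) to 6.20 ± 0.23, in 6 of 6 arrays. Its DIO-SC mean lay below 4.90, the cut for dim genes, so the size of the rise is less certain. Cth (1426243_at), the enzyme that makes cysteine and hydrogen sulfide, rose by 0.78 ± 0.11 (adjusted p = 3.9e-05) in 6 of 6 arrays, to 5.31 ± 0.32, where RW-SC hearts stood at 5.39 ± 0.18. Hspa1b changed by -1.57 ± 0.26 (adjusted p = 0.000476) and Ptgds (1423859_a_at), a prostaglandin D synthase, by -0.85 ± 0.11 (adjusted p = 1.8e-06), each lower in 6 of 6 arrays. Nqo1 (0.19, adjusted p = 0.157), Hmox1 (-0.10, adjusted p = 0.709), Nppb (-0.30, adjusted p = 0.374) and Dbp (0.04, adjusted p = 0.881) were not past the threshold.

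With limma, 423 of 9295 genes passed, 340 higher and 83 lower, of which 3 rose and 5 fell at least 1.5-fold. After a further quantile normalization 358 passed, 240 higher and 118 lower. The count was 249 without DIO-SC 5, 221 without DIO-MS 5 and 248 without DIO-MS 6. Other robust rises were Ddit4l (0.72), a growth regulator of muscle, Bdnf (0.49), Pde7a (0.48), Crebrf (0.40) and the transcription factor Foxo3 (0.25), with adjusted p between 0.000476 and 0.011. Robust falls included the co-chaperones Hsph1 (-0.61, adjusted p = 0.00663) and Dnaja1 (-0.48, adjusted p = 0.00288), the retinol-binding protein Rbp7 (-0.51, adjusted p = 0.000523) and the cell cycle inhibitor Cdkn1a (-0.43, adjusted p = 0.00168).

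In DIO-MS 8 of the 42 lists passed, 1 up and 7 down. Heat shock had 7 of 23 genes lower, 0 higher, 16 not past and 14 past when adjusted over the list alone (adjusted p = 1.05e-13, and adjusted p = 0.0818 with an estimated correlation). The xenobiotic list of the aryl hydrocarbon receptor had 3 of 16 genes higher, 0 lower and 3 past when adjusted over the list alone (adjusted p = 0.000572, and adjusted p = 0.156 with an estimated correlation). The receptor Ahr rose by 0.43 (adjusted p = 0.00322) or, as the mean of its probe sets, by 0.24. Immediate early genes had 3 of 25 lower, 0 higher and 5 past when adjusted over the list alone (adjusted p = 0.000438, and adjusted p = 0.156 with an estimated correlation). Klf4 (-0.35, adjusted p = 0.00684) and Jund (-0.28, adjusted p = 0.0022) were among them. Extracellular matrix shifted down with 0 of 36 genes past and 0 past when adjusted over the list alone (adjusted p = 0.000438, and adjusted p = 0.739 with an estimated correlation). Timp1 was at -0.37 (adjusted p = 0.125).

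The other 4 lists that moved down in DIO-MS depended on single arrays. Glucocorticoid response had 2 of 26 genes higher, 2 lower and 5 past when adjusted over the list alone (adjusted p = 0.0266, and adjusted p = 0.678 with an estimated correlation). Without DIO-SC 2 (0.145), DIO-MS 4 (0.0824), DIO-MS 5 (0.052) or DIO-MS 6 (0.0638), the list was not past. Cell cycle had 1 of 14 genes lower, 0 higher and 1 past when adjusted over the list alone (adjusted p = 0.0221, and adjusted p = 0.678 with an estimated correlation). Without DIO-SC 2 (0.145) or DIO-MS 6 (0.0638), the list was not past. The unfolded protein response had 1 of 26 genes higher, 1 lower and 2 past when adjusted over the list alone (adjusted p = 0.0221, and adjusted p = 0.678 with an estimated correlation). Without DIO-SC 4 (0.0729), DIO-SC 8 (0.0602), DIO-MS 2 (0.0724) or DIO-MS 6 (0.116), the list was not past. Hypoxia had 1 of 27 genes higher, 0 lower and 4 past when adjusted over the list alone (adjusted p = 0.0334, and adjusted p = 0.678 with an estimated correlation). It was not past without DIO-SC 5 (0.0822), DIO-MS 1 (0.0647), DIO-MS 4 (0.0824) or DIO-MS 5 (0.0551), nor with dim genes kept (0.0659).

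Sidestream smoke in obese mice (DIO-SS against DIO-SC, the response to sidestream smoke on the high-fat diet) went with lower Hspa1b, Ptgds, Kcne1 and Dbp and higher Ddit4l, Cth and Cyp1a1. Hspa1b changed by -1.77 ± 0.24 (adjusted p = 9.61e-07, n = 8 and 8), from 9.54 ± 0.83 (SD) to 7.77 ± 0.26, where RW-SC hearts stood at 7.28 ± 0.13. Ptgds changed by -0.82 ± 0.10 (adjusted p = 1.03e-07), Kcne1 by -0.73 ± 0.14 (adjusted p = 0.000121) and Dbp by -0.49 ± 0.08 (adjusted p = 1.19e-05), and all 4 genes were lower in 8 of 8 arrays. Ddit4l rose by 1.08 ± 0.15 (adjusted p = 1.08e-06), Cth by 0.76 ± 0.11 (adjusted p = 1.2e-06) and Cyp1a1 by 0.74 ± 0.12 (adjusted p = 1.2e-05), each in 8 of 8 arrays.

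With limma, 2960 of 9295 genes passed, 2140 higher and 820 lower, of which 5 rose and 13 fell at least 1.5-fold. After a further quantile normalization 2075 passed, 1081 higher and 994 lower. Tfrc changed by -0.69 ± 0.18 (adjusted p = 0.00423), the metalloproteinase inhibitor Timp4 by -0.72 ± 0.14 (adjusted p = 0.000166) and Hspa1a by -1.32 ± 0.22 (adjusted p = 1.9e-05), each lower in 8 of 8 arrays. Robust rises included Rrad (0.57, adjusted p = 0.000208), which restrains calcium channels, and the drug efflux pump Abcb1a (0.56, adjusted p = 3.5e-07). Hmox1 was not past the threshold (-0.05, adjusted p = 0.745). Nqo1 rose by 0.24 (adjusted p = 0.00752) and was at 0.17 (adjusted p = 0.0879) after a further quantile normalization.

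In DIO-SS 6 of the 42 lists passed, 2 up and 4 down. Heat shock had 11 of 23 genes lower, 0 higher, 12 not past and 12 past when adjusted over the list alone (adjusted p = 1.69e-07, and adjusted p = 0.391 with an estimated correlation). Dnaja1 was at -0.55 (adjusted p = 2.22e-05). Immediate early genes had 8 of 25 lower, 1 higher and 9 past when adjusted over the list alone (adjusted p = 0.0066, and adjusted p = 0.391 with an estimated correlation). Jund (-0.42, adjusted p = 3.39e-07) and Nr4a1 (-0.46, adjusted p = 0.00909) were among them. The xenobiotic list had 8 of 16 genes higher, 0 lower and 8 past when adjusted over the list alone (adjusted p = 0.0149, and adjusted p = 0.436 with an estimated correlation). The cytochrome Cyp4b1 was at 0.38 (adjusted p = 4e-05). Autophagy and lysosome genes had 10 of 23 higher, 0 lower and 14 past when adjusted over the list alone (adjusted p = 0.0236, and adjusted p = 0.391 with an estimated correlation). Gabarapl1 (0.42, adjusted p = 1.79e-06), the cargo receptor Sqstm1 (0.33, adjusted p = 0.00022) and Ulk1 (0.24, adjusted p = 0.000171) were among them. Cell cycle had 2 of 14 genes lower, 0 higher and 2 past when adjusted over the list alone (adjusted p = 0.0339, and adjusted p = 0.736 with an estimated correlation). Ccnd1 was at -0.34 (adjusted p = 0.00146). T cell markers had 3 of 9 lower, 0 higher and 3 past when adjusted over the list alone (adjusted p = 0.0149, and adjusted p = 0.736 with an estimated correlation). Without DIO-SC 2, whose T cell marker mean was 0.98 where the other DIO-SC arrays reached 0.06, neither the T cell (0.0912) nor the cell cycle list (0.161) passed. Clock genes went both ways (7 higher and 6 lower), with a list median of 0.10 and a mean of -0.04, and were not past (adjusted p = 0.423).

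The 2 smokes also shared genes in DIO mice: 317 genes rose and 50 fell in both, where 78.3 and 7.3 would be shared by chance, and 0 went opposite ways. As in RW mice, these chance counts leave the shared control arrays out of account. The correlation across genes was 0.67, against 0.44 (between 0.05 and 0.73) in simulated unchanged groups that share the control arrays. The covariance was 0.0106 against 0.00299 in the simulation, and 0.00768 (r = 0.42) with the control arrays divided between the responses. Many genes changed one way with the diet and the other way with smoke: 247 genes raised by the diet fell with sidestream smoke in DIO mice and 693 lowered by it rose, where 56.7 and 285.3 would do so by chance. These comparisons share the DIO-SC arrays with opposite sign, which alone favours opposite changes, and the chance counts take no account of it. The values as a whole also shifted, with a median change over all genes of -0.0236 for the diet and 0.0423 for DIO-SS. After a further quantile normalization 823 genes rather than 1239 were lower with the diet, and 1081 rather than 2140 higher in DIO-SS. Shared and opposite changes were not counted again after that normalization. The correlation of -0.50 lay within the range of simulated unchanged groups (-0.48, between -0.77 and -0.13). The covariance was -0.0118 against a mean of -0.00309 in the simulation, for which no range was kept, so no excess over chance is concluded. It was -0.00896 (r = -0.34) with the shared arrays divided. With mainstream smoke the counts were 27 and 137 where 5.7 and 45.3 would be shared by chance, again leaving the shared arrays out of account. The correlation was -0.37 against -0.42 (between -0.75 and 0.14) in the simulation and -0.18 (between -0.35 and 0.12) with the arrays divided. The covariance was -0.00624 against -0.00295, and -0.00333 with the arrays divided.

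Sidestream against mainstream smoke in RW mice (RW-SS against RW-MS, whether the kind of smoke matters) differed in Dbp, among others, and in atrial transcripts. Dbp was lower with sidestream smoke by -0.70 ± 0.08 (adjusted p = 5.24e-07, n = 7 and 8) in 7 of 7 arrays. With limma, 541 genes passed, 204 higher and 337 lower, and the count was 292 without RW-MS 2 and 4 when only these groups were fitted. With the mean of the atrial list in the model 504 genes passed, and 295 of the 541 were among them. The clock list had 4 of 18 genes lower, 1 higher and 11 past when adjusted over the list alone (adjusted p = 0.0178, and adjusted p = 0.81 with an estimated correlation). Without RW-MS 8 (0.0535), RW-SS 1 (0.0616) or RW-SS 6 (0.0507), the list was not past. Glucocorticoid response had 2 of 26 genes higher, 0 lower and 6 past when adjusted over the list alone (adjusted p = 0.00677, and adjusted p = 0.81 with an estimated correlation). Proteasome genes had 4 of 23 lower, 0 higher and 5 past when adjusted over the list alone (adjusted p = 0.00493, and adjusted p = 0.81 with an estimated correlation). Interferon response had 2 of 26 genes higher, 0 lower and 2 past when adjusted over the list alone (adjusted p = 0.0107, and adjusted p = 0.81 with an estimated correlation). Without RW-SS 1 (0.0802) or RW-SS 7 (0.561), the list was not past. The atrial list, with 5 of 13 genes higher, 1 lower and 10 past when adjusted over the list alone (adjusted p = 0.00493, and adjusted p = 0.81 with an estimated correlation), carried the low values of RW-MS 2, 6 and 8. Without these 3 arrays the clock list (0.0925), the proteasome list (0.0925), the interferon list (0.194) and the atrial list (0.941) were not past, and with the atrial mean in the model 0 of the 5 lists passed. For the atrial list that outcome was fixed, since the mean is its own. Cyp1a1 was not past the threshold (-0.32, adjusted p = 0.109).

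In DIO mice (DIO-SS against DIO-MS, the same question on the high-fat diet) the kinds of smoke differed in Cyp1a1, Zbtb16 and Dbp, among others. Cyp1a1 was lower with sidestream smoke by -1.07 ± 0.13 (adjusted p = 1.55e-06, n = 8 and 6), the glucocorticoid-induced transcription factor Zbtb16 by -0.94 ± 0.16 (adjusted p = 0.001) and Dbp by -0.53 ± 0.08 (adjusted p = 0.000726), each in 8 of 8 arrays. With limma, 237 genes passed, 148 higher and 89 lower, and 106 passed after a further quantile normalization, 33 higher and 73 lower. Single arrays moved this count: it was 43, 27, 83, 37, 624 and 827 without DIO-MS 1 to 6 in that order, and 80, 76, 132 and 125 without DIO-SS 4, 5, 7 and 8. Clock genes had 4 of 18 lower, 0 higher and 9 past when adjusted over the list alone (adjusted p = 0.035, and adjusted p = 0.864 with an estimated correlation). Without DIO-MS 5 (0.115), DIO-MS 6 (0.156), DIO-SS 3 (0.09), DIO-SS 4 (0.0552) or DIO-SS 8 (0.0725), the list was not past, nor was it with dim genes kept (0.078). Extracellular matrix had 3 of 36 genes higher, 0 lower and 5 past when adjusted over the list alone (adjusted p = 0.0262, and adjusted p = 0.942 with an estimated correlation). Without DIO-MS 5 (0.115), DIO-MS 6 (0.116), DIO-SS 4 (0.13) or DIO-SS 5 (0.0557), the list was not past. Fibroblast markers had 1 of 15 higher, 0 lower and 4 past when adjusted over the list alone (adjusted p = 0.0262, and adjusted p = 0.942 with an estimated correlation). Without DIO-MS 5 (0.115), DIO-MS 6 (0.0959) or DIO-SS 4 (0.0836), the list was not past.

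The difference between the mainstream responses of the diets (interaction, the DIO effect minus the RW effect, the question of the series title) included Cyp1a1 and Hspa1b. Cyp1a1 gained 1.63 ± 0.17 more in DIO than in RW mice (adjusted p = 6.5e-08), from 4.38 to 6.20 in DIO and from 5.67 to 5.85 in RW hearts. Hspa1b differed by -1.71 ± 0.35 (adjusted p = 0.0144), and with only the groups compared it did not pass (adjusted p = 0.0788). Cth gained 0.86 ± 0.15 more (adjusted p = 0.0027), and Nr1d1, which fell in RW mice, differed by 0.65 ± 0.11 (adjusted p = 0.0027). The stress gene Gadd45g (-0.64 ± 0.13, adjusted p = 0.0106) and Cebpb (-0.61 ± 0.10, adjusted p = 0.000831) differed the other way, and Cebpb rose with smoke in RW mice from 9.47 to 9.91. Tfrc differed by 1.38 ± 0.27 (adjusted p = 0.00924), but by 0.49 (adjusted p = 0.123) as the mean of its probe sets. With limma, 21 genes passed, 14 higher and 7 lower, and 1057 had an unadjusted p under 0.05. The count was 32 without DIO-SC 8, 33 without RW-MS 1 and 35 without DIO-MS 1.

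For the mainstream interaction 6 of the 42 lists passed, 1 up and 5 down. Heat shock had 2 of 23 genes lower, 0 higher and 3 past when adjusted over the list alone (adjusted p = 7.21e-09, and adjusted p = 0.226 with an estimated correlation). Glucocorticoid response had 2 of 26 lower, 0 higher and 4 past when adjusted over the list alone (adjusted p = 2.64e-06, and adjusted p = 0.226 with an estimated correlation). Immediate early genes had 1 of 25 lower, 0 higher and 2 past when adjusted over the list alone (adjusted p = 0.0126, and adjusted p = 0.506 with an estimated correlation). Without RW-MS 7 (0.0629), the list was not past. Cell cycle genes (adjusted p = 0.0238, and adjusted p = 0.891 with an estimated correlation) and T cell markers (adjusted p = 0.0132, and adjusted p = 0.891 with an estimated correlation) had 0 members past, over all genes or adjusted over the list alone. Without RW-MS 7, whose T cell marker mean was 1.98 where the other RW-MS arrays reached 0.07, they were at 0.403 and 0.212, without DIO-SC 2 at 0.084 and 0.0656, and cell cycle was at 0.054 without DIO-MS 6. The atrial list (adjusted p = 0.000728, and adjusted p = 0.891 with an estimated correlation) also had 0 members past, over all genes or adjusted over the list alone, and carried the low values of RW-MS 2, 6 and 8. It was not past when RW-MS 2, 6 and 8 were left out (adjusted p = 0.677).

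For sidestream smoke the responses of the diets differed in many genes (interaction, the same question for sidestream smoke). Hspa1b, which fell in DIO mice and stood at 0.17 (adjusted p = 0.658) in RW mice, differed by -1.95 ± 0.35 (adjusted p = 0.000179). Ddit4 differed by -1.34 ± 0.25 (adjusted p = 0.000281) and Hmox1 by -0.68 ± 0.15 (adjusted p = 0.00123). Ddit4 and Hmox1 rose in RW mice, from 7.96 to 9.04 and from 6.58 to 7.21, and stood at 8.52 and 6.72 in DIO-SC and at 8.27 and 6.67 in DIO-SS hearts. Ddit4l differed by 1.03 ± 0.21 (adjusted p = 0.000687), Cyp1a1 by 0.88 ± 0.17 (adjusted p = 0.000377), Bdnf by 0.81 ± 0.15 (adjusted p = 0.000338) and Dbp by 0.54 ± 0.11 (adjusted p = 0.000697). Tfrc differed by 1.36 ± 0.27 (adjusted p = 0.000424), or by 0.48 as the mean of its probe sets. With limma, 2641 genes passed, 1700 higher and 941 lower, of which 25 and 44 differed at least 1.5-fold, and after a further quantile normalization 1544 passed, 658 higher and 886 lower.

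For the sidestream interaction 5 of the 42 lists passed, all down. Glucocorticoid response had 11 of 26 genes lower, 0 higher, 15 not past and 12 past when adjusted over the list alone (adjusted p = 9.27e-06, and adjusted p = 0.317 with an estimated correlation). Fkbp5 was at -0.68 (adjusted p = 0.0094) and at -0.45 as the mean of its probe sets. Red cell markers had 3 of 6 lower, 0 higher and 3 past when adjusted over the list alone (adjusted p = 0.02, and adjusted p = 0.783 with an estimated correlation). Without RW-SS 4 (0.0721), the list was not past. Heat shock had 4 of 23 lower, 1 higher and 4 past when adjusted over the list alone (adjusted p = 0.02, and adjusted p = 0.982 with an estimated correlation). Without DIO-SC 4 (0.0682) or RW-SS 6 (0.0748), the list was not past, nor was it with dim genes kept (0.12). Immediate early genes had 7 of 25 lower, 3 higher and 12 past when adjusted over the list alone (adjusted p = 0.0248, and adjusted p = 0.561 with an estimated correlation). Without DIO-SC 2 (0.0562), DIO-SC 5 (0.0588), RW-SS 5 (0.0531) or DIO-SS 8 (0.0567), the list was not past, nor was it with dim genes kept (0.174). T cell markers had 2 of 9 lower, 0 higher and 2 past when adjusted over the list alone (adjusted p = 0.02, and adjusted p = 0.982 with an estimated correlation). Without DIO-SC 2 (0.0641), the list was not past.

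Genes chosen for their smoke response in part of the RW mice carried over less to DIO mice for sidestream smoke. Over 100 random divisions of the RW arrays, the 200 genes with the smallest p in one part changed in the chosen direction by 0.35 in the held-out RW mice and by 0.12 in DIO mice. That is 34.7%, and the difference was -0.23 (bootstrap interval -0.30 to -0.12). For mainstream smoke the values were 0.22 and 0.13, or 58.9%, with a difference of -0.09 (interval -0.18 to 0.08). The shares depended on the number of genes chosen. With 50 genes the sidestream change was 0.48 in held-out RW and 0.22 in DIO mice (45.5%, interval of the difference -0.41 to -0.09), and with 500 genes it was 0.28 and 0.06 (22.6%, interval -0.26 to -0.10). The mainstream share was 51.5% with 50 and 60.9% with 500 genes, with intervals of -0.24 to 0.20 and -0.12 to 0.06. Responses of the diets that share no control arrays correlated across genes at 0.26 for mainstream smoke (0.02 in simulated unchanged groups, between -0.37 and 0.45) with a covariance of 0.00348 (0.000163 in the simulation). In both diets 80 genes rose and 32 fell where 9.7 and 3.3 would be shared by chance. For sidestream smoke the correlation was 0.10 (0.02 in the simulation, between -0.43 and 0.50) with a covariance of 0.00233 (0.000212). In both diets 370 genes rose and 187 fell where 249.3 and 106.3 would be shared by chance, while 198 rose in RW and fell in DIO mice (95.5 by chance), and 132 fell in RW and rose in DIO mice (277.4 by chance).

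Of the 42 lists, 22 were not past the threshold in any of the 9 comparisons. Among them were the oxidative stress list of the factor NRF2 (smallest adjusted p = 0.144), inflammation and cytokines (0.189), hypertrophy and fetal genes (0.0871), macrophage (0.0561) and neutrophil markers (0.0938), oxidative phosphorylation (0.209) and contractile genes (0.342). The NRF2 list had 7 genes higher, 3 lower and 11 past when adjusted over the list alone in RW-SS (adjusted p = 0.144), and 10 higher and 2 lower in DIO-SS (adjusted p = 0.423).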

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

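The tests of explanations for the 3 patterns weighed here, and the counts of other splits of the arrays, were chosen after the results were seen.

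The responses of RW and DIO hearts to smoke differed by the interaction test in 21 genes for mainstream and 2641 genes for sidestream smoke. For mainstream smoke the DIO effect exceeded the RW effect by 1.634 for Cyp1a1, 1.376 for Tfrc, 0.862 for Cth, 0.65 for Nr1d1 and 0.558 for Ahr, and it was lower by log2 differences of -1.712 for Hspa1b, -1.389 for Hspa1a, -1.129 for Ddit4, -0.642 for Gadd45g and -0.615 for Cebpb. The Ahr call ended without DIO-SC 2 (adjusted p = 0.0514), RW-MS 7 (0.0526), RW-MS 8 (0.05), DIO-MS 3 (0.051) or DIO-MS 6 (0.0623). The Ddit4 call ended without RW-SC 2, 3, 5 or 7, DIO-SC 1, 2, 3 or 6, RW-MS 4, 5 or 8, or DIO-MS 2, 4 or 5 (adjusted p between 0.0507 and 0.0788). The Hspa1a call ended without RW-SC 2, 3, 6, 7 or 8, DIO-SC 1, 2, 4 or 5, RW-MS 3, 4, 5, 7 or 8, or DIO-MS 2 to 6 (adjusted p between 0.05 and 0.0905). As the mean of its probe sets the difference was 0.493 (adjusted p = 0.123) for Tfrc and 0.317 (adjusted p = 0.0294) for Ahr, and Hspa1b did not pass with only the groups compared (adjusted p = 0.0788). List medians differed by -0.108 for heat shock, -0.128 for glucocorticoid response, -0.083 for immediate early genes, -0.127 for cell cycle, -0.442 for T cell markers and 0.535 for atrial markers. With an estimated correlation none of these 6 lists passed (adjusted p = 0.226 with an estimated correlation for heat shock and glucocorticoid response, 0.506 for immediate early genes and 0.891 for the other 3). Without RW-MS 7 immediate early genes (adjusted p = 0.0629), cell cycle (0.403) and T cell markers (0.212) did not pass, without DIO-SC 2 cell cycle (0.084) and T cell markers (0.0656) did not, and without DIO-MS 6 cell cycle did not (0.054). Atrial markers did not pass with RW-MS 2, 6 and 8 left out (adjusted p = 0.677). The count of genes was 32, 33 and 35 without DIO-SC 8, RW-MS 1 and DIO-MS 1.

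For sidestream smoke the DIO effect exceeded the RW effect by 1.36 for Tfrc (0.48 as the mean of its probe sets), 1.032 for Ddit4l, 0.883 for Cyp1a1, 0.807 for Bdnf, 0.772 for Rrad, 0.541 for Dbp and 0.438 for Col1a1. It was lower by log2 differences of -1.946 for Hspa1b, -1.655 for Bmp10, -1.336 for Ddit4, -1.288 for Hspa1a, -1.053 for Tent5c, -0.684 for Fkbp5 (-0.448 as the mean of its probe sets) and -0.682 for Hmox1. For Tfrc, the probe sets other than the brightest were not past the threshold. The Tent5c call ended without RW-SS 2 (adjusted p = 0.0509) or RW-SS 4 (0.0576). The Bmp10 call ended without DIO-SC 2, 3 or 8 or RW-SS 2, 4 or 7 (adjusted p between 0.0528 and 0.0635), and the Col1a1 call without RW-SC 1, 2 or 5, DIO-SC 1, 3 or 7, RW-SS 2, 3, 4 or 6, or DIO-SS 4, 5 or 7 (adjusted p between 0.0534 and 0.0852). List medians differed by -0.252 for glucocorticoid response, -0.106 for heat shock, -0.136 for immediate early genes, -0.324 for red cell markers and -0.416 for T cell markers. With an estimated correlation none of these 5 lists passed (adjusted p = 0.317 with an estimated correlation for glucocorticoid response, 0.982 for heat shock and T cell markers, 0.561 for immediate early genes and 0.783 for red cell markers). Single arrays ended the call of heat shock (DIO-SC 4, 0.0682, and RW-SS 6, 0.0748), immediate early genes (DIO-SC 2, 0.0562, DIO-SC 5, 0.0588, RW-SS 5, 0.0531, and DIO-SS 8, 0.0567), red cell markers (RW-SS 4, 0.0721) and T cell markers (DIO-SC 2, 0.0641).

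In 100 splits of the arrays into groups of the same sizes, the real one gave the largest count in each of the 9 comparisons (1 split of 100 as large, the real one itself). Only some of the possible splits were drawn, so 1 in 100 was the smallest share they could give. For the comparisons of 2 groups, chance seldom gave so many genes. For the interactions, smoke and air labels were mixed within each diet, which removes the smoke responses themselves. Those splits therefore cannot tell whether chance gave the difference between the responses. The real count and the highest other were 638 and 89 for RW-MS, 2288 and 269 for RW-SS, 423 and 135 for DIO-MS, 2960 and 1437 for DIO-SS, and 1882 and 460 for the diet. They were 541 and 317 for sidestream against mainstream smoke in RW mice, 237 and 29 in DIO mice, 21 and 1 for the mainstream and 2641 and 2 for the sidestream interaction.

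Single arrays far from the rest of their group were found in 27 of 240 groups of values (11.2%), where chance gives about 1 in 20, or 5%. The measure was the gap of the outermost array to its neighbour divided by the range of the group. For the correlation with the own group it was 0.609 for RW-SC 1, 0.76 for DIO-SC 2, 0.796 for RW-MS 7 and 0.574 for RW-SS 7. RW-SS 7 also stood apart in the 3' minus 5' difference of Actb (0.594) and Gapdh (0.888). T cell markers were high in DIO-SC 2 (0.779) and RW-MS 7 (0.833), B cell markers in RW-SC 1 (0.685) and RW-MS 7 (0.589), adipocyte markers stood apart in DIO-SS 8 (0.598), and epicardial markers in DIO-SC 2 (0.601), RW-MS 7 (0.57) and DIO-SS 8 (0.589). Among the genes of the panel, RW-MS 7 stood apart for Nqo1 (0.632), Hspa1b (0.584), Fkbp5 (0.702) and Lcn2 (0.566), and RW-SC 1 for Nqo1 (0.556) and Lcn2 (0.587). Others were DIO-MS 1 for Cyp1b1 (0.766) and Hspa1b (0.805), DIO-MS 2 for Pdk4 (0.672), RW-SS 2 for Vegfa (0.668) and Ucp3 (0.572), RW-SC 4 for Nppa (0.597) and DIO-SS 2 for Myh7 (0.669).

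Of 1684 probe sets that stand for no gene or for several, and that no comparison of genes used, some also passed the threshold. They numbered 74 for RW-MS, 373 for RW-SS, 40 for DIO-MS, 397 for DIO-SS, 270 for the diet, 111 and 34 for sidestream against mainstream smoke in RW and DIO mice, and 421 for the sidestream interaction.

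Heat shock genes were higher in DIO-SC than in RW-SC hearts and lower again in smoke-exposed DIO hearts, where the falls had adjusted p = 0.0818 with an estimated correlation for mainstream and 0.391 for sidestream smoke. A few arrays alone were not the cause, since 8 of 8 DIO-SC arrays had a list mean above the highest RW-SC array. The diet alone, whatever the exposure, would raise the list alike in air and smoke, but the difference between diets was 0.377 in air, 0.117 in mainstream and 0.176 in sidestream smoke (permutation p = 0.00064 and 0.00289, two-sided, 100000 resamples). These p values are approximate, since both use the same air arrays and the spread differed (SD 0.15 in DIO-SC and 0.035 in DIO-SS). The list was also picked from all the lists after its values were seen, and the p values were not adjusted for that choice. They therefore do not exclude the diet alone. By camera with an estimated correlation neither interaction of the list passed. With the preset correlation the sidestream one was not past without DIO-SC 4 (adjusted p = 0.0682) or RW-SS 6 (0.0748). Handling or the time of killing of the DIO-SC mice cannot be told apart from the group, because each mouse has 1 group and no times are given, and it may have contributed, since the immediate early list also rose by a mean of 0.167. A biological interplay of obesity and smoke stays open and untested.

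Atrial genes were lower in RW-MS than in RW-SC hearts. A fall of the group's mean size in every RW-MS heart is excluded, since 5 RW-MS arrays lay inside the RW-SC range of the list mean. Atrial tissue missing from part of the RW-MS hearts is a candidate explanation, since 3 arrays (RW-MS 2, 6 and 8) lay below every array of the other groups for each of the 4 called atrial genes, with Sln between 4.47 and 5.42 against 11.43 or more. A fall in every RW-MS heart, smaller in most, cannot be told apart, since for each of these 4 genes at least 3 of the 8 RW-MS arrays lay above the RW-SC mean, a number that neither needs nor forbids a small fall, while in the mean of all 13 atrial genes 1 RW-MS array lay above the RW-SC median. RW-MS 2, 6 and 8 count among the 8 and lay below, and the list mean was 0.16 in the other RW-MS arrays and 0.19 in RW-SC. The labels do not say how the hearts were dissected.

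Lipid synthesis genes were lower in DIO-SC than in RW-SC hearts (13 of 24 genes, with the list at adjusted p = 0.822 with an estimated correlation). With the mean of 10 fat markers in the model, 11 of the 13 lower genes stayed past the threshold, as Scd1 did (-2.88 ± 0.69 before and -1.67 ± 0.20 after, adjusted p = 2.94e-08). In that model, with a common slope for both diets, the markers did not account for the whole change of these 11. Fasn (from -2.18 to -1.16) and Elovl6 (from -1.73 to -0.88) shrank too, while Fdft1, chosen after its values were seen, did not (from -0.20 to -0.22). The other 2 were no longer past, since Thrsp moved from -0.95 to -0.37 (adjusted p = 0.0726) and Fads1 from -0.17 to -0.11 (adjusted p = 0.164). Less fat tissue on the DIO-SC hearts is not excluded, since a marker mean can leave part of a fat difference in the values. Lower synthesis within fat tissue carried along with the hearts could also contribute and cannot be told apart, since at the lowest fat value, with a slope for each diet, only Scd1 stayed past (-1.08, adjusted p = 0.00797), Fasn was at -0.60 (0.0755) and Elovl6 at 0.03 (0.965), while 1 of the 13 genes, Elovl6, had a different slope (-0.795, adjusted p = 0.0242). Lower synthesis in heart muscle itself, as a response to dietary fat, stays open.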

How the results depend on the processing

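Leaving out RW-MS 7 and RW-SS 7 together, the brown fat and Gapdh covariates, and for lists the leave-one-out, the atrial covariate and leaving out RW-MS 2, 6 and 8 were chosen after seeing the data.

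Counts of genes kept within 1.5 times of the reported ones under most alternatives, and the cause was not tested where they did not, except as stated. Using only the groups compared gave 402 genes for RW-MS and 4 for RW-SS against RW-MS, but more than reported for the diet (2196), DIO-SS (3453), DIO-SS against DIO-MS (298) and the sidestream interaction (2877). Testing every probe set gave 1011 genes for RW-SS against RW-MS and 403 for DIO-SS against DIO-MS. Array weights gave 714 for DIO-MS, 1964 for DIO-SS against DIO-MS and 48 for the mainstream interaction, and leaving out RW-MS 7 and RW-SS 7 gave 725 and 648 for the first 2 of these. A further quantile normalization gave 106 for DIO-SS against DIO-MS and 1544 for the sidestream interaction. DIO-SS against DIO-MS also came to 90 with the description number as a block and 418 with the atrial covariate, and the mainstream interaction to 37 with the Gapdh covariate. Nppa reversed, from -1.12 in RW-MS to 0.034 (adjusted p = 0.902) with the atrial covariate, which holds Nppa itself.

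With the title number as a replicate block, the counts were 582 for RW-MS, 2308 for RW-SS, 336 for DIO-MS, 2866 for DIO-SS, 1816 for the diet, 515 and 213 between smokes, and 18 and 2596 for the interactions, and all 52 list results past the threshold kept their call.

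Leaving out each array in turn gave 452 to 739 genes for RW-MS, 1951 to 2299 for RW-SS, 221 to 443 for DIO-MS, 2519 to 2965 for DIO-SS and 1571 to 1869 for the diet. RW-SS against RW-MS ranged from 292 to 722, DIO-SS against DIO-MS from 27 to 827, the mainstream interaction from 14 to 35 and the sidestream one from 2251 to 2773. The arrays behind changes over 1.5 times were DIO-SC 5 (249), DIO-MS 5 (221) and DIO-MS 6 (248) for DIO-MS, RW-MS 2 (292) for RW-SS against RW-MS, and DIO-SC 8 (32), RW-MS 1 (33) and DIO-MS 1 (35) for the mainstream interaction. For DIO-SS against DIO-MS they were DIO-MS 1 to 6 (43, 27, 83, 37, 624 and 827) and DIO-SS 4, 5, 7 and 8 (80, 76, 132 and 125).

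Of the results for named genes, leave-one-out kept 7203, made 44 pass and ended 337. Only the groups compared kept 384 and ended 37, the atrial covariate kept 403, ended 23 and reversed 1, quantile normalization kept 411 and ended 12, no filter kept 416 and ended 17, and the mean of all probe sets kept 412 and ended 17. Of the 52 list results, the estimated correlation kept 3 and ended 49, no filter ended 5, leaving out RW-MS 7 and RW-SS 7 ended 4, the brown fat covariate ended 0, leaving out RW-MS 2, 6 and 8 ended 9, the atrial covariate ended 12, and leaving out each array kept 910 results and ended 51. Of 199 other probe sets of called genes, 118 passed in the same direction and 0 in the opposite one. For genes near background, signal over background limits what the arrays can show.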

Other observations

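In smoke-exposed DIO hearts, Cth and Cyp1a1 rose from DIO-SC levels below those of RW-SC hearts. Both DIO-SC means lay below 4.90, the cut for dim genes, and may be near background. Cth stood at 5.39 ± 0.18 (SD) in RW-SC, 4.53 ± 0.27 in DIO-SC, 5.31 ± 0.32 in DIO-MS and 5.29 ± 0.16 in DIO-SS hearts, so that with both smokes it was near its RW-SC mean. Cyp1a1 stood at 5.67 ± 0.21 in RW-SC and 4.38 ± 0.23 in DIO-SC hearts, and at 6.20 ± 0.23 with mainstream and 5.13 ± 0.31 with sidestream smoke on the high-fat diet.

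Ddit4 and Cebpb, which respond to stress and glucocorticoids, had DIO-SC levels above RW-SC levels and did not rise further with smoke. Ddit4 stood at 7.96 in RW-SC, 9.04 in RW-SS, 8.52 in DIO-SC and 8.27 in DIO-SS hearts, and Cebpb at 9.47, 10.11, 9.85 and 9.60. Alas2 showed another order: it stood at 7.67 ± 0.14 in RW-SC and 8.83 ± 0.77 in RW-SS, but at 7.69 ± 0.35 in DIO-SC and 7.87 ± 0.31 in DIO-SS hearts.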
